A study of Bos taurus with 14 samples.

How the data were processed

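RNA of chronic Staphylococcus aureus mastitis cows and of matched healthy cows was compared on 14 arrays of 7 cow pairs, with mastitis RNA in Cy5 on 11 arrays and in Cy3 on 3. Groups, dyes and pairs were taken from the labels. File names of 5 arrays order or name the cows differently from the labels, and the labels were kept. The titles also give the same slide, 20b, for 2 arrays, 1 of cow pair 6 with mastitis in Cy3 and 1 of pair 7 with mastitis in Cy5. Whether either label is wrong was not tested, and both pairs are dye-swapped. Per the labels, flags mark bad and absent spots, and per the file headers the arrays were scanned on a GenePix scanner and measured with GenePix Pro 3.0.6.90.

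The values used were the foreground and background intensity of each spot in each channel and the background SD, which the authors deposited without normalization, per the file headers. The deposited files also give the percent of saturated pixels per spot, per the file headers, and spot flags, which are codes and not measurements. No more than 2 spots on any array had over 50 percent of pixels saturated in a channel. The deposited series table holds log2 ratios. Set against the scanner values they were the log2 ratio of background-subtracted medians, without centring, and already turned to mastitis over healthy on the arrays with mastitis in Cy3, with a correlation of 1 on each array, so none of scale, centring and direction stays unknown. Their column medians were -0.067 and 1.38 for cow pair 1, 0.58 and 0.58 for pair 2, 0.095 and 0.88 for pair 3, 0.15 and 0.095 for pair 4, -0.27 and 0.046 for pair 5, 0.18 and 0.063 for pair 6, and -0.39 and -0.47 for pair 7.

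Everything below was computed here with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with a span of 0.3, control spots having weight 0. Spots with a flag below 0 and control spots were then left out. Ratios were turned to mastitis over healthy by the dyes in the labels, the 4 spots of a probe were averaged, and the 2 arrays of a pair were averaged to 1 value. Probes with a value in at least 5 of 7 pairs were tested, which left 165 of 172. The mean of the pair values was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The dye effect was fitted on the array values with a dye term and a mastitis term and the cow pair as a random block, for 144 probes with at least 10 arrays and at least 1 array with mastitis in Cy3. The estimated correlation of the 2 arrays of a pair in that fit was 0.00214, so there the 2 arrays counted almost as separate replicates.

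Gene lists were tested with camera (preset correlation 0.01, and estimated), fry and an exact sign-flip permutation test of the list mean, all two-sided with adjustment over the lists. Camera and fry ran on the 134 probes with a value in all pairs, which left the interferon response list too small for them. Once the array's names were known, they were matched by hand to current symbols for 125 probes, 29 of them ambiguous. Of 123 symbols, 113 were in the gene table of assembly ARS-UCD2.0, which was used for names only. Of 24 lists, 6 had probes but under 3 tested, and 5 had none, namely JAK-STAT, MAP kinase, milk protein, red cell and platelet genes, which were not analysed here. The genome build and array sequences are not given in the sources used here, and no coordinates are printed.

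The genes named follow a rule written before the data were examined, as were the design, the lists and most alternatives. It takes 10 higher and 10 lower probes, first those past the threshold with 1 sign in at least 6 of 7 pairs and then those of lowest limma p, and the 2 probes of lowest p of each list, B actin and GAPDH. NRAMP1 was measured in 5 pairs, so it enters by its p. No probe passed the first part.

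Alternatives covered background correction, normalization, scaling, dim probes, spot flags, the dye effect, the dye orientation of arrays whose file names differ, the batch named in the titles, the variance model, the deposited ratios and leaving out each pair. Scan day was read from the file headers and used as a batch. The fits were tested on simulated data with the missing values of the real arrays and the SD of each probe, in 20 runs of 165 probes of which 40 were changed. For the mastitis comparison, 77.5 percent of probes changed by 0.5 on the log2 scale were called in the right direction and 94.5 percent of those changed by 1, with 1.08 percent of unchanged probes called. Where a dye effect of 1 and no mastitis effect was simulated, the pair means called 11.25 percent of all those probes as mastitis. The fit with a dye term called 0 percent, but only of the probes it covers, which leaves out NRAMP1, MIP-1b, IFNaR and TLR4. Without a value on arrays with mastitis in Cy3, a dye effect cannot cancel in the pair means, so neither share describes such probes. A list moved by 0.5 was called by camera in 100 percent of the runs, with 12 lists per run. The simulated noise was independent between probes and between arrays, unlike the real data. There the estimated correlation within a list reached 0.955 for housekeeping probes, so real recovery can be lower than these shares. A first simulation used a smaller, median-based spread and recovered more probes, and the recovery given here is that of the later one.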

Results

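The series holds 14 two-colour cDNA arrays that compare chronic Staphylococcus aureus mastitis cows with healthy Holstein control cows. Mastitis is inflammation of the udder. Each of the 7 infected cows was matched with 1 control cow, so the 14 animals form 7 cow pairs. Each pair was hybridised on 2 arrays, with RNA of the infected cow in one dye and RNA of the control in the other. The labels do not say on which array blood mononuclear cells or milk cells were used, so the cell type behind each ratio stays open. Mastitis RNA carried Cy5 on 11 arrays and Cy3 on 3 arrays, and only cow pairs 5, 6 and 7 had both orientations. The array carries 172 probes for immune, endocrine and housekeeping genes, each spotted 4 times.

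Signal differed strongly between arrays. On the 6 arrays of the third scan day, median Cy5 brightness was 10.8 to 52.1 times the local background, and 14 to 23 of 720 spots per array were marked as poor by the scanner software. On the 6 arrays of the second scan day that multiple was 1.42 to 2.13, and 146 to 222 spots were marked. The 2 arrays of the first scan day had 78 and 265 marked spots. All 3 arrays with mastitis in Cy3 were of the second scan day. Cow pairs 5, 6 and 7, with both orientations, had no array of the third scan day. A difference between dye-swapped and other pairs can therefore follow signal as well as dye. Over probes, the log2 ratios had an SD of 0.076 to 0.20 on arrays of the second scan day and 0.33 to 1.49 on those of the third. Of 172 probes, 165 to 167 were above background on the arrays of the third scan day, 105 to 130 on those of the second and 115 and 155 on those of the first. On the arrays of the third scan day, negative control probes also gave Cy5 signal, with medians over background of 2.05 to 4.03 on the log2 scale. Being above background there therefore does not show signal specific to a gene. The number of arrays limits the precision of each value. P-values of the fits on pair means rest on the spread between these cow pairs, moderated by limma with the spread of other probes. Cow pairs 5 and 6 have arrays of the second scan day only, so the spread between pairs cannot be told apart from the difference in signal. Fits on the 14 array values, with a dye term, the random block or scan day as a block, also rest on the spread between arrays. Their 2 arrays per pair hold the same 2 animals, so the 7 pairs remain the replicates.

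The first comparison asked which genes differ between infected and healthy cows. NRAMP1 (SLC11A1), a divalent metal transporter of the phagosome, was lower in mastitis, with a mean log2 ratio of -0.76 ± 0.056 (SD, n = 5 pairs) or 1.69-fold, and fell in 5 of 5 measured pairs (limma adjusted p = 0.00463). Its limma SE of 0.073 was above that SD, so its p rests largely on spread borrowed from other probes. NRAMP1 was the only 1 of 165 tested probes past the threshold. None was past it in the higher direction, and 72 probes had an unadjusted limma p under 0.05, 33 higher and 39 lower. NRAMP1 had no usable spot on any of the 3 arrays with mastitis in Cy3, so all 8 arrays that measured it carry mastitis RNA in Cy5. With 5 pairs the exact sign-flip test cannot go below p = 0.0625, which NRAMP1 reached.

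Other probes with low limma p-values did not pass the adjustment over pair means. On the lower side MIP-1b (CCL4), a chemokine that attracts monocytes and lymphocytes, had a mean log2 ratio of -0.49 ± 0.11 (SD, n = 5 pairs; limma adjusted p = 0.0552). The interferon alpha receptor probe IFNaR was at -0.41 ± 0.095 (SD, n = 5) and TLR4, the receptor for bacterial lipopolysaccharide, at -0.38 ± 0.060 (SD, n = 5), both with a limma adjusted p of 0.0671. Like NRAMP1, these 3 probes were measured on 8 arrays, all with mastitis in Cy5. IL8 (CXCL8), which attracts neutrophils, was at -0.84 ± 0.66 (SD, n = 7) and was negative in 6 of 7 pairs. NFAT3, MIP-1a, MCP-1, CCR3 and TCRe (named here as CD3E) had mean log2 ratios of -0.33 (n = 5 pairs), -0.30 (n = 6), -0.31 (n = 7), -0.28 (n = 5) and -0.23 (n = 7). NFAT3 and MIP-1a had no usable spot on arrays with mastitis in Cy3, and CCR3 had a value on 1 of those 3 arrays. Of the 10 higher probes of lowest limma p, those with the largest means were PPRL at 0.99 ± 0.93 (SD, n = 6), the insulin receptor probe IR at 0.93 ± 0.81 (SD, n = 6), IGF1 at 0.86 ± 0.76 (SD, n = 6) and TIR at 0.65 ± 0.68 (SD, n = 7). The means of the other 6 of these, IL2, IL12-35 (IL12A), NOS, TGFbR-1, IL12Rb2 and IL12R, were 0.34, 0.33, 0.33, 0.31, 0.28 and 0.26. The housekeeping probes B actin and GAPDH were at -0.84 ± 0.91 (SD, n = 7) and -0.50 ± 0.63 (SD, n = 7). Without the 2 arrays of widest ratios, a setting chosen after seeing the data, PPRL was at 0.46, IR at 0.77, IGF1 at 0.44, TIR at 0.39, B actin at -0.34 and GAPDH at -0.16. Array weights were estimated on the 7 pair means, so they weigh cow pairs. With them the means of PPRL, IR, IGF1, TIR, B actin and GAPDH were 0.24, 0.27, 0.26, 0.15, -0.21 and -0.13, and IL8 was at -0.45. Within the second scan day they were 0.041, 0.11, 0.14, 0.064, -0.062 and -0.042, and IL8 was at -0.018. With 2 arrays turned after their file names IR was at 0.20. With 2 or with 4 turned, 0 of 165 probes had an unadjusted limma p under 0.05. With the 14 arrays and the cow pair as a random block, 15 of 145 probes passed, 12 higher and 3 lower, at a lowest limma adjusted p of 0.0492. Among them IL2, IL12-35, TGFbR-1, IL12Rb2, IL12R and IR were higher and MCP-1 and TCRe lower. With array weights none of these 8 passed, and IL2, IL12-35, TGFbR-1, IL12Rb2, IL12R, MCP-1 and TCRe were at 0.14, 0.13, 0.13, 0.10, 0.10, -0.12 and -0.12. Within the second scan day none passed either, and these 7 were at 0.061, 0.046, 0.066, 0.017, 0.035, -0.087 and -0.084. With array weights MIP-1b, TLR4 and IFNaR passed as lower beside NRAMP1, and with an intensity trend MIP-1b and IFNaR did. With marked spots left out, these probes have no value in cow pairs 5 and 6. None of them passed with plain background subtraction, median centring, scaling between arrays, marked spots kept or the deposited ratios.

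**Figure D1:**
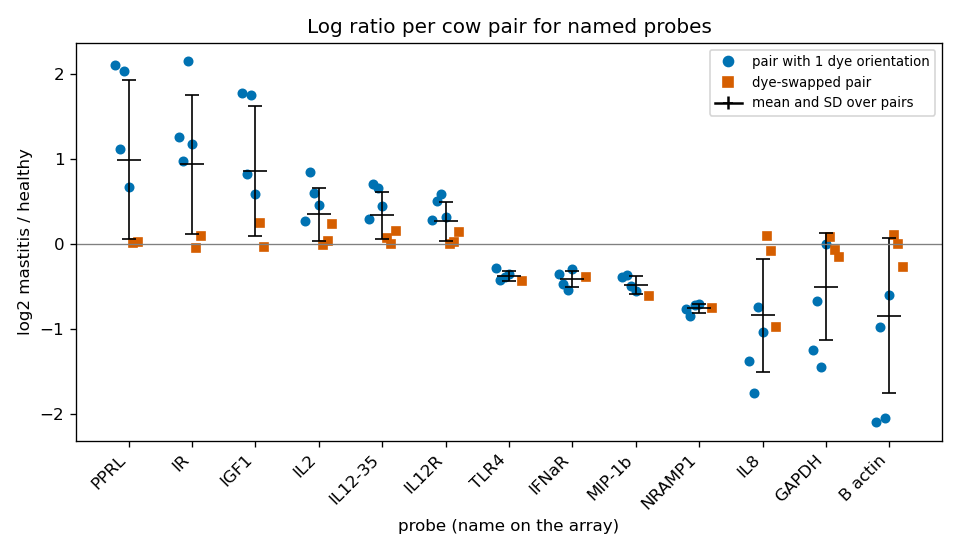
Log2 mastitis over healthy per cow pair (vertical axis) for 13 named probes (horizontal axis), with circles for pairs of 1 dye orientation, squares for dye-swapped pairs, and the mean with SD in black. NRAMP1 lies near its mean of -0.76 in 5 pairs, its square coming only from an array with mastitis in Cy5, and the dye-swapped pairs 5 and 6 lie near 0 for IR and B actin.

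The count differed between sets of arrays, models and processing choices. Limma found 0 of 144 probes past the threshold with the dye effect as a term, with 13 at an unadjusted p under 0.05, and 0 of 134 in the 3 dye-swapped pairs alone, none at an unadjusted p under 0.05. With scan day as a block, chosen after seeing the data, 65 of 144 probes passed, 38 higher and 27 lower, and NRAMP1 had too few arrays to be tested. That fit used the 14 array values with the cow pair as a random block, not the 7 pair means. Within the third scan day, whose 6 arrays all had mastitis in Cy5 and are those without the batch mark in the titles, 43 of 169 probes passed over 4 pairs, 28 higher and 15 lower, while within the second, where 3 arrays had each orientation, 0 of 139 passed over 4 pairs by limma, and 0 had an unadjusted p under 0.05. The difference between scan days was not tested, and negative control probes also gave signal on the arrays of the third. The first scan day, with 2 pairs, which like the second was taken alone only after seeing the data, gave 1 probe, IL8, at -1.58. NRAMP1 could not be tested when cow pair 1, 2, 3, 4 or 7 was left out, since it then had too few pairs, and the count was 0 without each of these. It was also no longer past the threshold with plain background subtraction, where it was at -1.07, with median centring, at -1.34, with the marked spots kept, at -0.43, with scaling between arrays, at -0.41, with the deposited ratios, at -0.48, or within the first scan day, at -0.78. File names of 3 of the 8 arrays that measured NRAMP1 give the cows in the opposite order to the labels. With 2 arrays turned after their file names NRAMP1 was at -0.33 (limma adjusted p = 0.963), and with 4 turned at -0.025 (limma adjusted p = 0.996).

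Of 24 gene lists, 13 had at least 3 tested probes and 12 could be tested with camera. No list passed camera after adjustment, with the preset or an estimated correlation, and none passed fry or the exact sign-flip test after adjustment. Chemokines and their receptors had negative means for 13 of 15 probes, with a list mean of -0.19 ± 0.14 (SD, n = 7 pairs) and a negative mean in 7 of 7 pairs (exact sign-flip p = 0.0156, the smallest 7 pairs can give; adjusted p = 0.0677). Adjusted over the list alone, 5 of the 15 were lower, namely IL8, MIP-1b, MIP-1a, MCP-1 and CCR3, against 0 over all probes. An unadjusted limma p under 0.05 was found for 6 of the 15, against 72 of all 165 tested probes. The list mean was -0.037, -0.037 and -0.088 in cow pairs 5, 6 and 7. Camera took in the 9 of the 15 with a value in all pairs, without MIP-1b, MIP-1a and CCR3, and gave an adjusted p of 0.465, or 0.725 with an estimated correlation.

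Th1 cytokines and their receptors had positive means for 6 of 7 probes and a list mean of 0.20 ± 0.19 (SD, n = 7 pairs), positive in 7 of 7 pairs (exact sign-flip p = 0.0156; adjusted p = 0.0677). The list mean was 0.15 to 0.46 in cow pairs 1 to 4, but 0.0018, 0.0063 and 0.085 in pairs 5, 6 and 7. Adjusted over the list alone, 5 of its probes were higher, among them IL2, IL12R and IL12Rb2. Its camera adjusted p was 0.182, and 0.725 with an estimated correlation. The interferon response list had 3 probes and a mean of -0.12 ± 0.087 (SD, n = 7 pairs), negative in 7 of 7 pairs (exact sign-flip p = 0.0156; adjusted p = 0.0677), with IFNaR and IFNtp lower and INFa higher when adjusted over the list alone. Pattern recognition probes had negative means in 4 of 4 cases, with a list mean of -0.18 ± 0.13 (SD, n = 7 pairs). Among the 4, CD14 was at only -0.021 ± 0.27 (SD, n = 7), higher in 3 pairs and lower in 4. The interferon response and pattern recognition means were -0.14 ± 0.11 and -0.22 ± 0.076 (SD, n = 4) within the third scan day, -0.031 ± 0.026 and -0.018 ± 0.052 (SD, n = 4) within the second, and -0.14 and -0.46 within the first, with 2 pairs. In the 3 dye-swapped pairs they were -0.065 ± 0.057 and -0.11 ± 0.18 (SD, n = 3). These means are not balanced for dye: IFNaR and TLR4 had no usable spot on arrays with mastitis in Cy3. Their pair 7 values of -0.39 and -0.44 come from the array with mastitis in Cy5. The pattern recognition mean was 0.029, -0.058 and -0.31 in cow pairs 5, 6 and 7. Other list means over the dye-swapped pairs have the same limit where a probe lacks such spots. Within the pattern recognition list TLR4 passed over the list alone and TLR2 had a mean log2 ratio of -0.19.

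Housekeeping probes had a list mean of -0.55 ± 0.62 (SD, n = 7 pairs; exact sign-flip p = 0.0469, adjusted p = 0.122), and all 5 were lower when adjusted over the list alone. PRL19, a ribosomal protein probe by its name, was at -0.72 ± 0.66 (SD, n = 5), with no usable spot on arrays with mastitis in Cy3. The pituitary, growth hormone and IGF list had positive means for 8 of 11 probes and a list mean of 0.24 ± 0.25 (SD, n = 7 pairs), positive in 5 of 7 pairs (exact sign-flip p = 0.0938). Within the 3 dye-swapped pairs the means of these lists were -0.044 ± 0.088 and -0.0083 ± 0.064 (SD, n = 3). Within the third scan day they were -1.21 ± 0.92 and 0.54 ± 0.24 (SD, n = 4), and within the second -0.066 ± 0.084 and 0.0030 ± 0.037 (SD, n = 4). Th1 and chemokine means were 0.32 ± 0.13 and -0.32 ± 0.19 (SD, n = 4) within the third scan day, and 0.031 ± 0.054 and -0.057 ± 0.049 (SD, n = 4) within the second. Within the first, with 2 pairs, they were 0.26 and -0.28. In the 3 dye-swapped pairs they were 0.031 ± 0.047 and -0.054 ± 0.029 (SD, n = 3).

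None of the remaining tested lists passed the exact sign-flip test after adjustment. Proinflammatory cytokines were at -0.095 ± 0.15 (SD, n = 7), with IL12-35 at 0.33 and IL1antag (IL1RN), the interleukin 1 receptor antagonist, at -0.51. T cell markers were at -0.10 ± 0.16 (SD, n = 7), with TCRa at -0.33. Apoptosis genes were at -0.13 ± 0.18 (SD, n = 7), with Bcl-2 at -0.21 (n = 5 pairs) and Bcl-XL at -0.35. Antigen presentation was at -0.031 ± 0.060 (SD, n = 7), with TAP2 at -0.22 and MHC-DQ at -0.23. B cell and immunoglobulin probes were at -0.035 ± 0.077 (SD, n = 7), with IgM at -0.40 (n = 5 pairs) and IgJ at -0.35. Bcl-2 and IgM had no usable spot on arrays with mastitis in Cy3. Monocyte and macrophage probes were at 0.17 ± 0.29 (SD, n = 7), with FcRgIII at 0.26, an FcRgII probe at 0.28 and CD14 at -0.021. Th2 and regulatory probes had a mean of -0.028 ± 0.11 (SD, n = 7), a median member of 0.017, an upward camera direction and a mean of 0.014 with scaling between arrays, so their direction was not settled. Among them IL4R was at 0.24 and IL10Ra, named only IL10R in part of the files, at -0.62 ± 0.87 (SD, n = 7). IL10Ra ran from -2.11 in cow pair 1 to 0.030 in pair 5. Within the third scan day monocyte and macrophage probes were at 0.43 ± 0.30, apoptosis genes at -0.28 ± 0.19, T cell markers at -0.27 ± 0.30 and proinflammatory cytokines at -0.23 ± 0.26 (SD, n = 4). Within the second these means were 0.0080 ± 0.040, -0.016 ± 0.12, -0.028 ± 0.044 and 0.016 ± 0.048 (SD, n = 4), and in the 3 dye-swapped pairs -0.073 ± 0.15, 0.010 ± 0.11, -0.012 ± 0.041 and 0.018 ± 0.060 (SD, n = 3). Within the first, with 2 pairs, they were -0.24, -0.015, 0.039 and -0.069. Antigen presentation, B cell and Th2 means were -0.088 ± 0.088, -0.017 ± 0.13 and -0.084 ± 0.18 within the third scan day, and 0.024 ± 0.022, -0.035 ± 0.023 and 0.023 ± 0.055 within the second (SD, n = 4).

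Lists with fewer than 3 tested probes were not tested as lists. Granzyme, of cytotoxic cells, was at 0.35 ± 0.51 and Lactoferrin, a granulocyte protein, at 0.24 ± 0.31 (SD, n = 7). Both were highest in cow pair 3, at 1.36 and 0.84. ICAM3 and CD44 were at -0.46 ± 0.84 and -0.0065 ± 0.048 (SD, n = 7), and the receptor probes ER and PGR at 0.70 ± 1.08 and -0.71 ± 0.92 (SD, n = 7). C3 was at 0.12 ± 0.21 (SD, n = 7), C4 at 0.36 ± 0.49 (SD, n = 6) and SOD at -0.28 ± 0.29 (SD, n = 7). NOS and SOD, the 2 probes of the stress list, had limma adjusted p-values of 0.107 and 0.109 over all probes.

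The second comparison measured the dye effect, since the dyes were unequally balanced. Limma found 0 of 144 probes past the threshold for Cy5 over Cy3, and 15 at an unadjusted p under 0.05. Across probes, which are not independent replicates, the fitted dye effect correlated at 0.982 with the mean log2 ratio of the pairs, and so did the fitted mastitis effect at 0.989. Both terms have the same sign on the 11 arrays with mastitis in Cy5, which also dominate the pair means. On the 3 arrays with mastitis in Cy3 the log2 ratios had an SD over probes of only 0.076 to 0.13. Both correlations therefore follow largely from the design and do not separate dye from mastitis. The 3 arrays with mastitis in Cy3 had a median Cy5 brightness of 1.93 to 2.13 times the local background.

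The third comparison asked whether the 2 arrays of a cow pair gave the same ratios. Across probes the correlation was 0.419, 0.900, 0.531 and 0.636 in cow pairs 1 to 4, whose arrays share 1 orientation, and 0.0950, 0.206 and 0.119 in the dye-swapped pairs 5 to 7. In the swapped pairs the sign depended on the processing: with the deposited ratios it was -0.398, -0.686 and 0.00481, with the marked spots kept -0.223, -0.0364 and 0.0643, and with median centring 0.0962, 0.0394 and -0.00376. Arrays of different pairs with the same orientation correlated with a median of 0.386 over 54 comparisons, from -0.404 to 0.919. Arrays of different pairs with opposite orientation, turned by the labels, correlated with a median of -0.189 over 30 comparisons, and 29 of these were below 0. The lowest was -0.715.

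**Figure D2:**
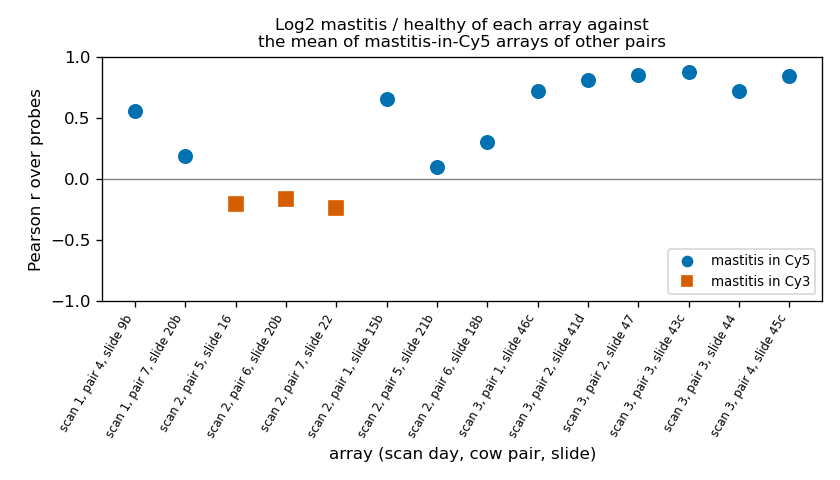
Pearson correlation over probes (vertical axis) of each array's log2 mastitis over healthy with the mean of mastitis-in-Cy5 arrays of other cow pairs, for the 14 arrays by scan day (horizontal axis). The 11 arrays with mastitis in Cy5 (circles) lie between 0.0981 and 0.881, and the 3 with mastitis in Cy3 (squares) between -0.239 and -0.163.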

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

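The counts over sign patterns were planned, and all other tests of explanations in this part were chosen after the result was seen, as were the rules by which the tests below were read. In 2 of 60 groups of pair values 1 cow pair stood apart, where chance gives about 1 in 20. NFAT3 was at -0.50 in cow pair 3 against -0.32 to -0.25 in the other 4 pairs measured. MIP-1a was at -0.61 in cow pair 1 against -0.32 to -0.14 in the other 5.

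Probes placed as negative controls, which no comparison used, gave signal on the 6 arrays without the batch mark in the titles. Their median Cy5 brightness over local background on the log2 scale was 2.50 for 17KDV, 3.30 for pACYC177, 2.05 for CSF and 4.03 for INS, against 0.14 for buffer spots, whose highest value was 0.33. On the 8 arrays with that mark the medians were -0.013, 0.013, -0.025 and 0.46, against -0.022 for buffer spots, whose highest value was 0.041. INS was above the buffer spots on 8 of these 8 and reached 2.66.

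Arrays of different cow pairs shared 1 pattern of log2 ratios over probes. A dye bias is a candidate explanation: turned by the labels, the 3 arrays with mastitis in Cy3 correlated at a median of -0.206 with the mean of the other pairs' mastitis-in-Cy5 arrays. A mastitis difference shared by the pairs needs values above 0, and the highest was -0.163, but it stays open with wrong dye labels on these 3 arrays, which would give the same sign. Both a dye bias and wrong labels need the 2 arrays of a swapped pair, turned by the labels, to correlate below 0, and the values were 0.0950, 0.206 and 0.119. With the deposited ratios they were -0.398, -0.686 and 0.00481, so their sign depends on the processing and the 3 explanations cannot be told apart.

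NRAMP1 was lower in mastitis in each of the 5 pairs that measured it. With the marked spots kept, its log2 Cy5 over Cy3 was below 0 on 14 of 14 arrays and averaged -0.19 on the 3 arrays with mastitis in Cy3, the sign a dye bias would give. The probe was above background on 0 of those 3, so dye and mastitis cannot be told apart for it. Of the 64 sign patterns of the 7 pairs, 4 gave as many probes as the real 1, and the highest other gave 1; turning pairs 5 and 6, in which NRAMP1 has no value, cannot change its call, so the patterns are too few for a share under 0.05. For gene lists the real value was 0, which 64 of 64 patterns must reach, and the highest other gave 2, so that count tests nothing.

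The hormone axis list lay above the housekeeping list by 0.78 ± 0.84 (SD, n = 7 pairs) on the log2 scale (exact sign-flip p = 0.0312, unadjusted). These 2 lists were set against each other after their means were seen, so that p is no independent support. The difference was 1.35 ± 0.67 in the 4 pairs with 1 dye orientation and 0.036 ± 0.060 in the 3 dye-swapped pairs, above 0 in 2 of 3. The dye-swapped pairs had no array of the third scan day, so dye orientation and signal cannot be told apart here. The probes were split into 2 classes by the ratio on the brightest array of cow pair 1, 87 with a high and 84 with a low Cy5 over Cy3, and 8 of 12 hormone probes and 0 of 5 housekeeping probes were in the high class. With each class centred on its own mean the difference over pairs 2 to 7 was 0.29 ± 0.40 (SD), against 0.61 ± 0.78 before. Since the difference was under 1 SD before centring, this test decides nothing. A mastitis difference stays open, since the swapped pairs neither all lie above 0 nor have a mean at or below 0.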

How the results depend on the processing

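Alternatives chosen after seeing the data were scan day as a block, the first and second scan days alone, only arrays with mastitis in Cy5, the swapped arrays turned against the labels, leaving out the 2 arrays of widest ratios, centring of probe classes, probes complete in all pairs, and the correlation of the arrays of a pair with marked spots kept or plain subtraction. The arrays without the batch mark in the titles are the 6 of the third scan day, a setting that was planned. The count of probes past the threshold was 1 and ran from 0 to 65. It was 0 with plain background subtraction, with median centring without loess, with scaling between arrays, with marked spots kept, with the dye effect as a term, with the 3 dye-swapped pairs alone, with 2 or 4 arrays turned after their file names, with the marked batch alone, with the deposited ratios, without the 2 widest arrays, with complete probes and within the second scan day. It was 15 with 14 arrays and the cow pair as a random block, 43 without the marked batch, 3 with an intensity trend, 4 with array weights, 2 with the swapped arrays turned against the labels and 65 with scan day as a block. Leaving out each pair gave 0 to 1. NRAMP1 had too few values to be tested with the dye term, the random block, scan day as a block, the dye-swapped pairs, the marked batch alone, the second scan day, complete probes, without the 2 widest arrays and without pair 1, 2, 3, 4 or 7; for the other settings the cause was not tested. NRAMP1 kept its sign wherever it was tested, with an adjusted limma p from 0.00124 to 0.996. Gene lists were tested again only with an estimated correlation, fry, no background correction, median centring, dim probes left out, the dye term, the dye-swapped pairs, 2 arrays turned, the swapped arrays turned against the labels, each pair left out, probe classes centred, the 2 widest arrays left out and scan day as a block. Under these no list passed, except 1, Th1 cytokines, with scan day as a block, a fit on array values (camera adjusted p = 0.0149). Over the pair means that list had an adjusted p of 0.725 with an estimated correlation, and with each probe class centred the lowest adjusted p of any list was 0.542. No probe passed for the dye effect by limma under any of its 4 alternatives, with 6 to 74 at an unadjusted p under 0.05. The median correlation of the arrays of a pair stayed within 1 SD, from 0.376 to 0.589, but swapped pairs fell below 0: pairs 5 and 6 with the deposited ratios (-0.398 and -0.686) and with marked spots kept (-0.223 and -0.0364), and pair 7 with median centring (-0.00376). The tested list means kept their sign under the other background, normalization, scaling and spot choices, except Th2. Their size changed: Th1 was at 0.11 with scaling between arrays and 0.50 with median centring, against 0.20. Pattern recognition was at -0.35 with plain subtraction, against -0.18. With scaling, monocyte and macrophage, hormone axis and housekeeping means were 0.049, 0.098 and -0.26, against 0.17, 0.24 and -0.55. The deposited ratios were not centred, and their median over all probes lay 0.39 higher. The low signal over background of the first and second scan days limits ratios from them. On 1 array of the first, 155 of 172 probes were above background.

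Over 1286 values of the 46 named probes under alternatives, 50 changed sign, none of them past the threshold, and the cause was not tested. With 2 arrays turned after their file names, C4 was at -0.0022, FcRgII at -0.026 and ICAM3 at 0.064. With 4 turned, C4 was at -0.0022, FcRgII at -0.0082, TCRe at 0.0055, IL8 at 0.016, NFAT3 at 0.023, MIP-1a at 0.028, MIP-1b at 0.029 and Bcl-2 at 0.037. In the 3 dye-swapped pairs, C3 was at -0.011, Granzyme at -0.012, FcRgII at -0.014, FcRgIII at -0.017, ER at -0.30, TAP2 at 0.015, IgJ at 0.024, PGR at 0.028 and ICAM3 at 0.035. In the marked batch alone, FcRgII was at -0.014, Bcl-XL at 0.031, ICAM3 at 0.033, CD44 at 0.037, IL10Ra at 0.043 and GAPDH at 0.050. Within the first scan day, ER was at -0.16, CD44 at 0.050, PRL19 at 0.064, GAPDH at 0.13, IL10Ra at 0.13 and ICAM3 at 0.26. Within the second, FcRgII was at -0.00068, C3 at -0.021, C4 at -0.030, CD44 at 0.012, Bcl-XL at 0.020 and MHC-DQ at 0.10. With the deposited ratios, IgM was at 0.030, Bcl-2 at 0.079, MHC-DQ at 0.34 and CD44 at 0.65. With median centring, C4 was at -0.064 and CD44 at 0.29. CD44 was also at 0.00046 with the swapped arrays turned against the labels, 0.0012 with plain subtraction, 0.0060 with scan day as a block and 0.058 without the 2 widest arrays, and ER was at -0.037 with array weights. Leaving out each pair turned only CD44, which ran from -0.020 to 0.0033 and was above 0 without pair 1.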

Other observations

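The split of probes into 2 classes by the brightest array of cow pair 1 was chosen after seeing the data. On the 13 other arrays the median log2 Cy5 over Cy3 of the high class was above that of the low class in 13 of 13, by 0.11 to 3.12. It was so on the 3 arrays with mastitis in Cy3, by 0.11 to 0.17, and on the other 10 with mastitis in Cy5, by 0.12 to 3.12. All 7 Th1 probes were in the high class, as were 6 of 13 antigen presentation probes and 3 of 15 chemokine probes, while 12 of 15 chemokine probes, 4 of 5 pattern recognition probes and all 5 housekeeping probes were in the low class.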
